A study of Mus musculus with 6 samples.

How the data were processed

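Total RNA was isolated with Trizol and made into libraries with Illumina protocols, per the labels' protocols, and how mRNA was selected is not given in the sources used here. The libraries came from anti-CD3 and anti-CD28 stimulated splenic CD8 T cells of OT-I mice, 3 labelled WT and 3 labelled KO. The authors deposited 1 table of raw read counts per gene, with 49492 rows named by gene symbol and 1 column per library. HTSeq 0.9.1 and DESeq2 are named without a role, and mm10 as the genome build, per the submitters' processing notes. The aligner, the gene annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. The table holds no rows for unassigned reads, and 0 columns were left unused. Of its symbols, 47240 are names in the reference gene table. Coordinates, lengths and GC content were taken by symbol from GENCODE M21 on GRCm38, which is the mm10 assembly.

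Samples were grouped by the genotype in their titles. Total counts ran from 41311346 to 47851445 per library. Every pair of libraries differed by more than sampling noise, with a mean chi-square per gene from 21.2 to 58.0 over genes with at least 200 counts in the pair, so no library was counted as a duplicate. The replicate numbers, 1 to 3 and 4 to 6, are not shared between the genotypes and pair no libraries. CPM are the deposited counts scaled to a common library size with TMM factors. Intervals are at the 95% level and cover the spread between libraries, and floors are 3 counts and cover counting error only.

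The comparison was fitted to the deposited counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust glmQLFit and glmQLFTest). Benjamini-Hochberg adjusted p under 0.05 over 15186 tested genes counted as a call. A log2 fold is the libraries labelled KO over those labelled WT, and its SE was derived from the fold and the F statistic. In all, 38 gene lists were written for spleen, T cell stimulation and NIK, and 35 with at least 3 tested genes were tested. The lists covered noncanonical NF-kB components and NF-kB inducible genes, T cell activation and function, growth and metabolism, stress and interferon responses, the cell cycle, sex-linked and mitochondrially encoded transcripts, and markers of other splenic cells. The table holds no row for 5 of the list genes. Lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists. Fry's directional p tests whether a list's genes move on balance in 1 direction, and its mixed p whether they change in either direction. Neither fry p compares a list with other genes. Library measures were compared with exact two-sided permutation tests.

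The genes named were set by a rule fixed before the data were examined, as were the lists, the design and most alternatives. The rule took 12 genes whatever their values. It took up to 8 genes per direction with the largest fold among called genes with a mean of at least 5 CPM, non-overlapping groups and a plain gene symbol, or the 3 with the smallest p in a direction with none. It took up to 4 called members of each list, or the member with the smallest p where none was called. Other genes were named after their values were seen, and the text says so.

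Alternatives were RLE and upper-quartile factors, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, an adjusted p under 0.01, glmTreat against a fold of 1.2, mitochondrial, immunoglobulin and ribosomal protein genes left out, and each library left out in turn. Chosen after seeing the data were a term for the sex of the mice, a fit without robust estimation, removal of each library's trend with gene length and GC content (96.8% of tested genes had both), and the mitosis list score as a term. The procedure was tested on simulated counts drawn independently for each gene, with the means, dispersions and depths of the same libraries. In all, 14969 genes passed the filter. EdgeR called 40.3% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 92.4% of those changed 4-fold, with 18 false calls. DESeq2 called 49.3%, 67.2% and 92.4%, with 50 false calls. In genes, edgeR recovered 27, 43 and 61 beside its 18 false calls, and DESeq2 33, 45 and 61 beside its 50. For both tools the share of false calls was above the level that an adjusted p under 0.05 sets, and more so for DESeq2. A simulated list changed 1.3-fold was called by camera with the preset and with the estimated correlation, and 0 other lists were called with the preset. Its genes were drawn independently, whereas genes of many real lists varied together. The simulation therefore cannot show how often the preset calls unchanged lists in the real libraries. One gene is not reported here.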

Results

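RNA was sequenced from CD8 T cells purified as naive cells from the spleens of OT-I mice and stimulated through the T cell receptor. OT-I mice carry a transgenic receptor, built with a Vβ5 beta chain, that recognises an ovalbumin peptide. Libraries labelled WT came from wild type OT-I mice and libraries labelled KO from NIK-CD4Cre-OT-I mice. NIK is the kinase, encoded by Map3k14, that starts the noncanonical NF-kB pathway, and Cre driven by Cd4 sequences acts in developing T cells. The mice were 6 to 8 weeks old. The cells were kept for 24 hours on anti-CD3 (1 µg/ml) with anti-CD28 (1 µg/ml) in the medium. There were 3 libraries per genotype, WT replicates 1 to 3 and KO replicates 4 to 6, and the single comparison asks how the transcriptome of stimulated CD8 T cells differs when T cells lack NIK. The labels do not say that each library came from its own mouse, so p-values measure the spread between these libraries.

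Gene counts summed to 45012963, 46084518 and 46548251 in WT replicates 1, 2 and 3, and to 47851445, 43675448 and 41311346 in KO replicates 4, 5 and 6. At these depths a count of 3 corresponds to 0.0627 to 0.0722 normalised CPM (counts scaled to a common library size), for counting error only. Total counts (exact two-sided permutation p = 0.5), genes with at least 1 count (exact p = 0.4) and the mitochondrially encoded share (exact p = 0.8) did not separate the groups. The 50 most abundant genes took 11.8% ± 0.325 (SD, n = 3) of counts in the libraries labelled WT and 11.4% ± 0.0857 (SD, n = 3) in those labelled KO, with exact permutation p = 0.1, the smallest that 3 against 3 libraries can give. Both groups mixed the sexes of the mice. Xist, expressed from the inactive X chromosome, had 92901, 90998 and 82938 counts in WT replicates 1 and 3 and KO replicate 6. It had 22, 27 and 38 counts in WT replicate 2 and KO replicates 4 and 5, which carried 9956 to 11368 counts of Y-linked genes.

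Map3k14, the targeted gene (chromosome 11, 103219762 to 103267472, minus strand, GRCm38), was detected at similar levels in all 6 libraries. It had 2406, 2992 and 3025 counts in WT replicates 1 to 3, and 2425, 2837 and 2271 counts in KO replicates 4 to 6. The mean was 61.5 CPM ± 6.81 (SD, n = 3) in the libraries labelled WT and 56.6 CPM ± 7.10 (SD, n = 3) in those labelled KO. The log2 fold was -0.12 (SE 0.11), with an adjusted p of 0.81 in edgeR's quasi-likelihood test, and the 95% interval of the fold ran from 0.766 to 1.11. The count covers the whole gene and a conditional allele can remove only some exons, so it checks the labels only in part. It did not set the groups apart, and every direction given here is between libraries as they are labelled.

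Other members of the pathway that NIK controls showed no called difference. Of 15 noncanonical NF-kB components, edgeR called 0, with 2 higher in the libraries labelled KO at an unadjusted p under 0.05, and DESeq2 also called 0. Nfkb2, the precursor that NIK signalling processes to p52, stood at 397.2 CPM ± 8.58 against 411.4 CPM ± 5.53 (WT and KO labels, SD, n = 3 each), a log2 fold of 0.05 with an edgeR adjusted p of 0.79. Its partner Relb had a log2 fold of -0.02 (edgeR adjusted p = 0.94), and the estimate turned positive without WT replicate 2. Ltb, a ligand of this pathway, had the smallest p on the list, at 196.8 CPM ± 5.70 against 238.2 CPM ± 28.6 (SD, n = 3 each; edgeR adjusted p = 0.61). The list as a whole was not called by camera (adjusted p = 0.15; adjusted p = 0.74 with an estimated correlation), although it passed as higher without WT replicate 2 (adjusted p = 0.029) and without KO replicate 4 (adjusted p = 0.035). Among 25 NF-kB inducible genes edgeR called 0 over all genes with all 6 libraries, with 4 higher and 4 lower at an unadjusted p under 0.05, DESeq2 called 1, the chemokine Ccl4, and edgeR without WT replicate 1 called 1, the chemokine Ccl3. Adjusted over the list alone, 1 was higher and 2 were lower. These were Nfkbie, an inhibitor of NF-kB that was named after its values were seen (log2 fold 0.22), and Ccl3 (log2 fold -0.90) and Ccl4 (log2 fold -0.69). Camera did not call this list (adjusted p = 0.30; adjusted p = 0.76 with an estimated correlation).

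**Figure D1:**
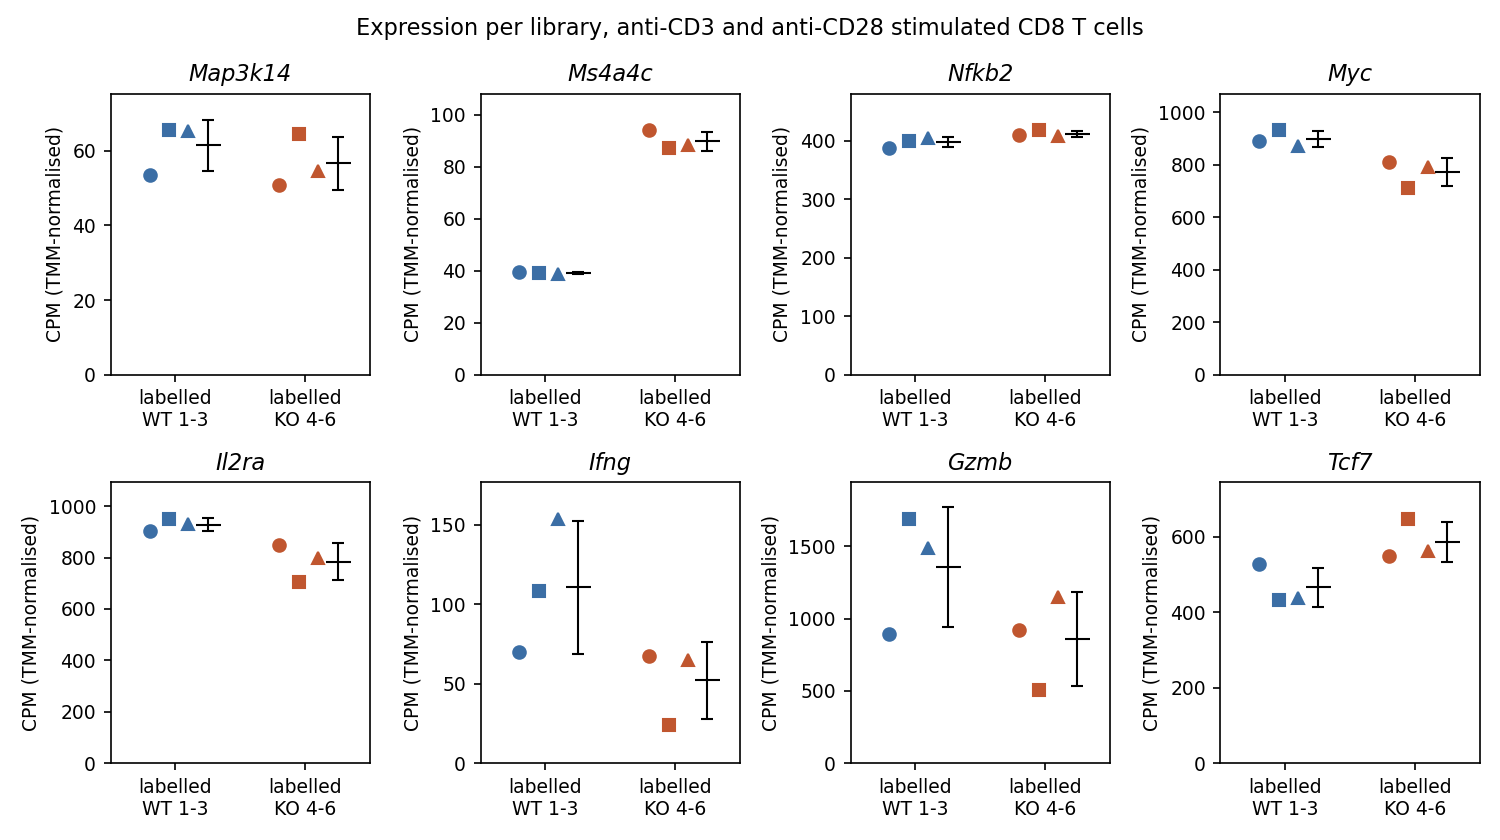
Expression of 8 genes in each library (y axis, TMM-normalised CPM, starting at 0). Coloured points are libraries, in the order WT replicates 1 to 3 and KO replicates 4 to 6 (circle, square, triangle), and black bars give the mean and SD of 3 libraries per label. Ms4a4c lies between 38.7 and 39.6 CPM in the libraries labelled WT and between 87.4 and 94.1 CPM in those labelled KO, whereas Map3k14 and Gzmb overlap between labels.

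Across all genes, 1 of 15186 passed the test. Ms4a4c (chromosome 19, 11404770 to 11427246, plus strand, GRCm38), a membrane protein of the MS4A family, rose 2.30-fold in the libraries labelled KO. It was measured at 39.6, 39.1 and 38.7 CPM in WT replicates 1 to 3, and at 94.1, 87.4 and 88.3 CPM in KO replicates 4 to 6. Its log2 fold was 1.201 (SE 0.05), with an edgeR adjusted p of 4.2e-04. MS4A genes resemble each other, so how reads were divided among them is uncertain. At an unadjusted p under 0.05 there were 1103 genes, 580 higher and 523 lower, and 12.8% of tested genes had non-overlapping groups, where chance gives 10%. The other splits of the 6 libraries into equal groups gave from 124 to 2065 genes at this p. The splits with 1323, 1727 and 2065 genes exceeded the real count, so 1103 is no evidence by itself of a genotype difference. DESeq2 called 96 genes (64 higher and 32 lower), limma-voom called 1, and edgeR called 119 (52 higher and 67 lower) once WT replicate 1 was left out. On the other splits DESeq2 called from 0 to 388 genes, and the splits with 259 and 388 exceeded the 96. The count of 96 is thus no evidence by itself of a genotype difference. Without a low-count filter edgeR called 10, all higher.

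EdgeR called 0 genes lower when genotype was the single term and all 6 libraries were used, against 523 lower at an unadjusted p under 0.05 and 32 lower in DESeq2. With the mitosis score as a further term it called 1 lower, Trbv12-1 (log2 fold -0.89, adjusted p = 0.016). The 3 lower genes with the smallest p were Mme, Trbv12-1 and Ncs1. Mme, the surface peptidase CD10, was at 6.37 CPM ± 1.13 against 1.67 CPM ± 0.700 (WT and KO labels, SD, n = 3 each; edgeR adjusted p = 0.48; DESeq2 adjusted p = 1.9e-08). Trbv12-1, a beta chain variable segment of the Vβ5 family, was at 220.6 CPM ± 40.7 against 130.5 CPM ± 4.18 (SD, n = 3 each; edgeR adjusted p = 0.48; DESeq2 adjusted p = 2.8e-06). Without WT replicate 1 it was also called by edgeR (log2 fold -0.60, adjusted p = 0.015). It closely resembles other Vβ5 segments, so its read assignment is uncertain. The labels do not give the dose of the receptor transgene in either genotype, so a difference in dose and a difference in expression cannot be separated in this value. Ncs1, a neuronal calcium sensor, was at 60.1 CPM ± 2.00 against 49.6 CPM ± 1.18 (SD, n = 3 each, edgeR adjusted p = 0.53, DESeq2 adjusted p = 0.015).

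Several genes that edgeR did not call with the low-count filter and genotype as the single term were called by DESeq2. Those given here are a choice among such genes, and were named after their values were seen. Kit, the stem cell factor receptor, had 4.01 CPM ± 1.13 against 17.4 CPM ± 6.70 (SD, n = 3 each; DESeq2 adjusted p = 1.7e-09; edgeR adjusted p = 0.48). The retinoic acid receptor gene Rarg (log2 fold 0.84), the ETS factor Elk3 (log2 fold 0.59), the cathepsin gene Ctss (log2 fold 0.64), the co-receptor gene Slamf6 (log2 fold 0.61) and the kinase gene Dclk1 (log2 fold 2.66) had higher values in all 3 libraries labelled KO. All of these 5 were called by DESeq2, and by edgeR without WT replicate 1 (adjusted p from 0.010 for Dclk1 to 0.043 for Ctss). With all 6 libraries edgeR called Rarg (adjusted p = 0.0026), Elk3 (0.0044), Ctss (0.0038) and Slamf6 (0.019) without a low-count filter, and Dclk1 (0.016) with the mitosis score as a term.

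Genes set in advance for T cell activation and function were not called by edgeR or DESeq2, and their values were as follows. Ifng, the effector cytokine interferon gamma, was at 110.7 CPM ± 42.0 against 52.2 CPM ± 24.3 (WT and KO labels, SD, n = 3 each), a log2 fold of -1.08 (edgeR adjusted p = 0.69). Granzyme B (Gzmb) was at 1357 CPM ± 416.5 against 860.3 CPM ± 325.0 (edgeR adjusted p = 0.70). Il2 was at 17.2 CPM ± 3.93 against 12.9 CPM ± 4.34 (edgeR adjusted p = 0.75). Myc had a log2 fold of -0.22 (edgeR adjusted p = 0.60) and the IL-2 receptor chain Il2ra one of -0.24 (edgeR adjusted p = 0.61), and for both every library labelled KO lay under every library labelled WT. Tcf7, the factor of naive and memory T cells TCF-1, had a log2 fold of 0.33 (edgeR adjusted p = 0.60) with every library labelled KO above those labelled WT. Among metabolic genes, the glucose transporter Slc2a1 had a log2 fold of -0.25 (edgeR adjusted p = 0.78), hexokinase Hk2 one of -0.23 (edgeR adjusted p = 0.71) and G6pdx, the entry enzyme of the pentose phosphate pathway, one of -0.01 (edgeR adjusted p = 0.96), which turned positive without KO replicate 6. Leaving out 1 library gave -0.45 (without WT replicate 1) to -0.11 (without WT replicate 2) for Slc2a1, and -0.35 to -0.13 without the same libraries for Hk2.

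Gene lists gave a broader picture that depended on the test. Camera with a preset correlation of 0.01 called 18 of 35 lists, 5 higher and 13 lower in the libraries labelled KO. With an estimated correlation camera called 0 lists, and fry called 0. Estimated correlations lay above the preset for every called list except the antioxidant list (0.00401). They reached 0.943 for S phase, 0.928 for mitosis, 0.896 for hypoxia and 0.836 for ribosomal protein genes. The preset takes genes of such lists as nearly independent, which these values contradict. With the preset, every other split of the 6 libraries into equal groups also gave calls, from 8 to 19 lists. The count of 18 is thus no evidence by itself of a genotype difference. Of 667 genes on these lists edgeR called 0 over all genes with all 6 libraries, with 33 higher and 60 lower at an unadjusted p under 0.05. DESeq2 called 7 higher and 9 lower, and edgeR without WT replicate 1 called 6 higher and 20 lower. The calls of 8 lists held in all 6 fits that left out 1 library.

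**Figure D2:**
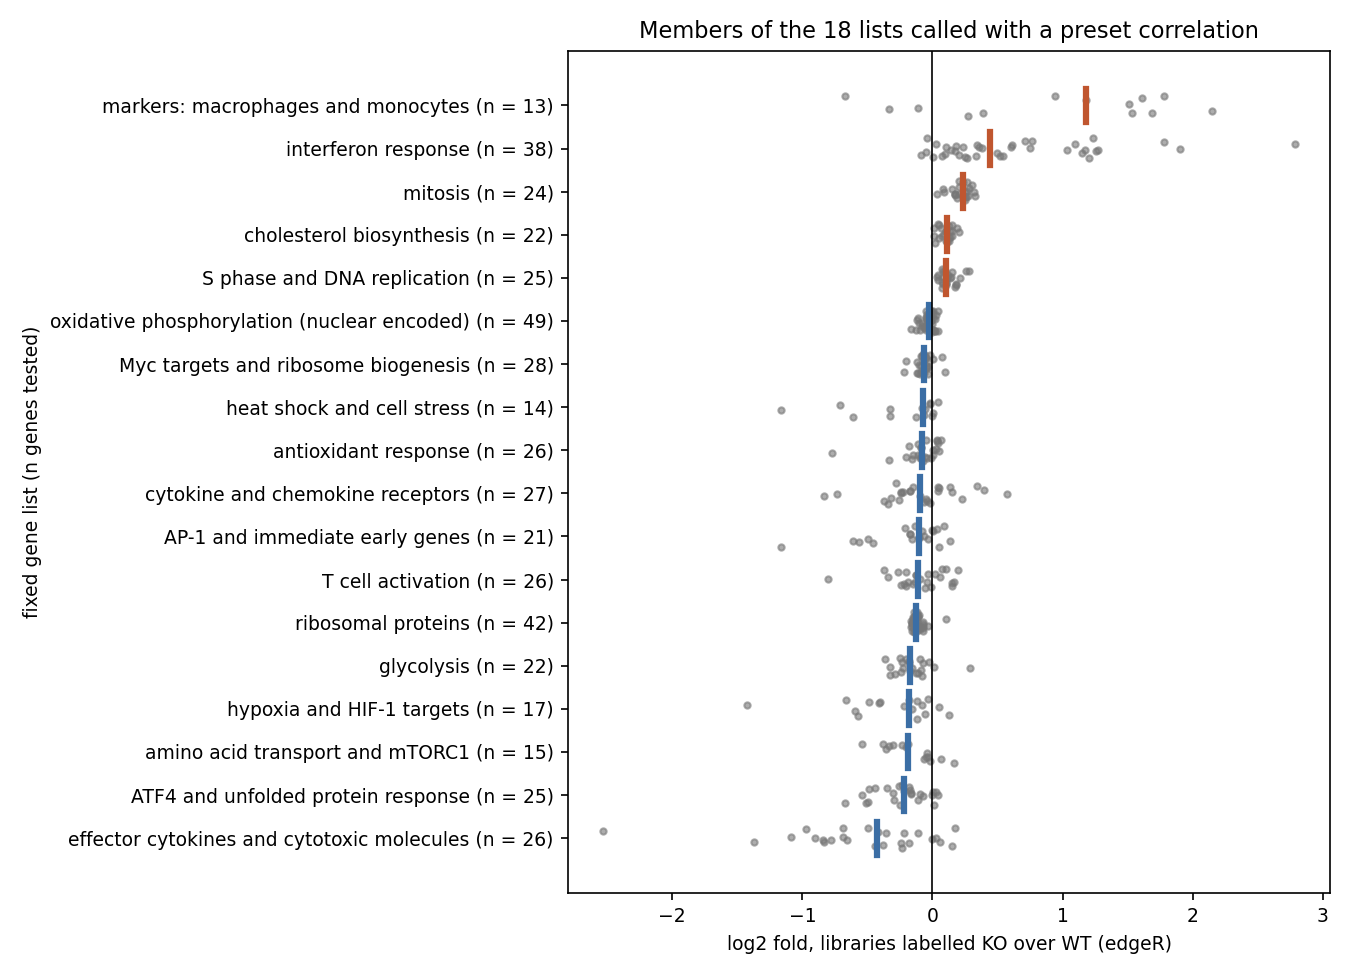
Log2 fold of each tested member (grey points; x axis, libraries labelled KO over WT, edgeR) for the 18 lists that camera called with a preset correlation, with the median of each list as a coloured bar. The median is 1.18 for markers of macrophages and monocytes, 0.44 for interferon response and -0.43 for effector cytokines and cytotoxic molecules. Members of most other lists lie closer to 0.

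Interferon-stimulated genes had a positive median that was called with the preset correlation alone. Of 38 tested, 35 had positive estimates, the median log2 fold was 0.44, and camera called the list (adjusted p = 3.3e-10; adjusted p = 0.72 with an estimated correlation and 0.68 with fry). The list score of KO replicate 5 (-0.0795) lay under that of WT replicate 2 (-0.0663). With all 6 libraries no member was called over all genes by edgeR, against 13 higher at an unadjusted p under 0.05, 6 called higher by DESeq2, and 1 called higher by edgeR without WT replicate 1. Adjusted over the list alone, 7 were higher. Oas1a, a sensor of double-stranded RNA from a family of similar genes, was at 1.23 CPM ± 0.417 against 4.61 CPM ± 1.90 (WT and KO labels, SD, n = 3 each; edgeR adjusted p = 0.53). Named after their values were seen, the chemokine Cxcl10 was at 7.65 CPM ± 1.46 against 18.0 CPM ± 6.35 (edgeR adjusted p = 0.53), Ifit1 had a log2 fold of 1.204 and the GTPase gene Iigp1 one of 0.50. KO replicate 6 had the highest list score, 0.76 log2 units above the mean of the 6 libraries, and without it the median log2 fold was 0.18 (camera adjusted p = 2.1e-06). Without WT replicate 1 the median was 0.29 (camera adjusted p = 2.1e-04). Across the 6 libraries the score correlated with that of the macrophage and monocyte list without Ly6c2 (r = 0.757), and KO replicates 6 and 4 ranked highest in both.

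Cell cycle and sterol lists also had positive medians. All 24 mitosis genes had positive estimates, with a median log2 fold of 0.23 (camera adjusted p = 5.4e-06; adjusted p = 0.74 with an estimated correlation). The mitotic kinesin gene Kif11 had the smallest p, at 105.0 CPM ± 26.1 against 131.5 CPM ± 18.3 (WT and KO labels, SD, n = 3 each; edgeR adjusted p = 0.71). WT replicate 1 had the highest mitosis score of all libraries, and the median was 0.48 without it, 0.11 without WT replicate 2 and 0.14 without WT replicate 3. All 25 S phase and DNA replication genes had positive estimates (camera adjusted p = 0.0019; adjusted p = 0.76 with an estimated correlation), with Ccne2, cyclin E2, leading at a log2 fold of 0.28 (0.46 without WT replicate 1 and 0.16 without WT replicate 2). All 22 cholesterol biosynthesis genes did so too (camera adjusted p = 0.0029; adjusted p = 0.76 with an estimated correlation), led by the sterol desaturase gene Sc5d at a log2 fold of 0.15. The S phase call was lost without KO replicate 4 (adjusted p = 0.93), WT replicate 2 (0.25) or WT replicate 3 (0.060), and the cholesterol call without KO replicate 4 (0.75) or WT replicate 2 (0.13). With all 6 libraries no member of these 3 lists was called by edgeR or DESeq2, and 0 had an unadjusted p under 0.05. Without WT replicate 1 edgeR called 4 mitosis genes higher.

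**Figure D3:**
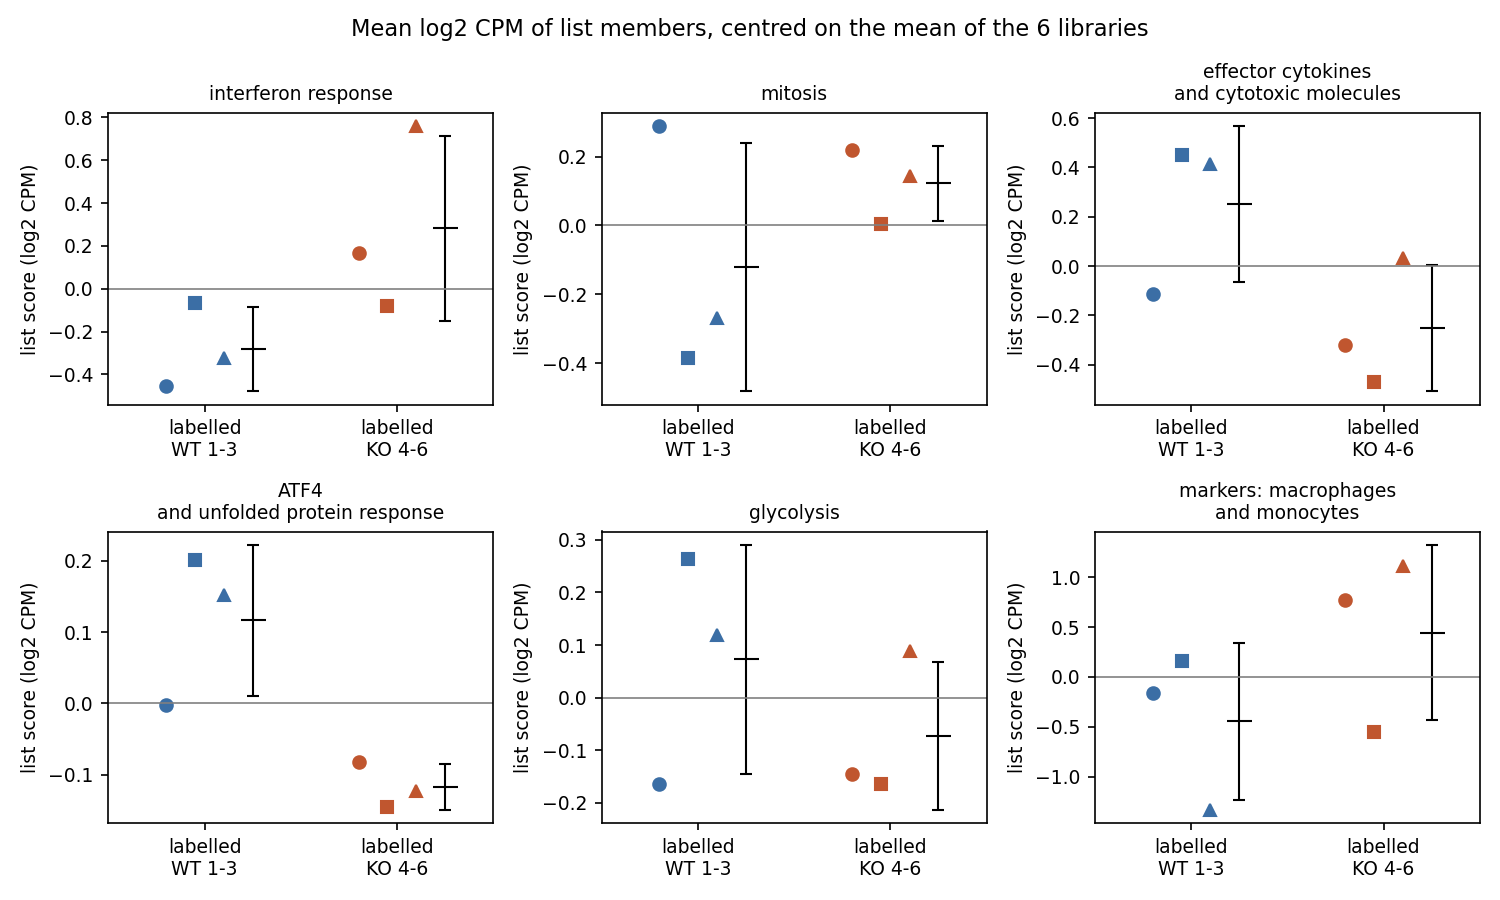
Score of 6 gene lists in each library (y axis, mean log2 CPM of list members centred on the mean of the 6 libraries). Points are libraries (circle, square, triangle for WT replicates 1 to 3 and KO replicates 4 to 6) and black bars the mean and SD of 3 libraries per label. WT replicate 1 stands apart from the other WT libraries in the mitosis, effector and glycolysis scores, and KO replicate 6 has the highest interferon score.

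Effector genes had a negative median that was called with the preset correlation alone. The list of effector cytokines and cytotoxic molecules also holds the transcription regulators Eomes, Id2, Prdm1, Tbx21 and Zeb2. Of its 26 tested genes, 22 had negative estimates, with a median log2 fold of -0.43 (camera adjusted p = 4.7e-08, and adjusted p = 0.69 with an estimated correlation and 0.63 with fry). The list score of KO replicate 6 (0.0319) lay above that of WT replicate 1 (-0.112). At an unadjusted p under 0.05 there were 8 lower members, DESeq2 called 2 lower, and edgeR called 0 over all genes with all 6 libraries and 3 lower without WT replicate 1. Adjusted over the list alone 1 was lower, the chemokine Ccl4 at 377.0 CPM ± 70.6 against 234.3 CPM ± 26.4 (WT and KO labels, SD, n = 3 each; edgeR adjusted p = 0.53; DESeq2 adjusted p = 5.2e-04). Other effector genes, named after their values were seen, were Ccl3 (578.9 CPM ± 174.5 against 310.0 CPM ± 40.2, SD, n = 3 each), Xcl1 (log2 fold -0.49), the growth factor gene Csf2 (log2 fold -0.97) and perforin, Prf1 (log2 fold -0.38).

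Lists for activation and signalling had smaller medians in the same direction. In the T cell activation list 18 of 26 genes had negative estimates (camera adjusted p = 0.0032; adjusted p = 0.72 with an estimated correlation), led by Stat5a, a transducer of IL-2 signals, at 302.1 CPM ± 7.21 against 262.4 CPM ± 6.70 (SD, n = 3 each; edgeR adjusted p = 0.53; DESeq2 adjusted p = 0.042). Among cytokine and chemokine receptors 18 of 27 did (camera adjusted p = 0.018; adjusted p = 0.74 with an estimated correlation), led by Cxcr6 at a log2 fold of -0.83. Among AP-1 and immediate early genes 16 of 21 did (camera adjusted p = 0.0016; adjusted p = 0.69 with an estimated correlation), led by the stress-induced factor Atf3 at a log2 fold of -0.50. Heat shock and cell stress genes had 12 of 14 (camera adjusted p = 0.0019; adjusted p = 0.43 with an estimated correlation), led by Gadd45a at a log2 fold of -0.71. With all 6 libraries no member of these 4 lists was called by edgeR over all genes, and without WT replicate 1 Atf3 was (adjusted p = 0.037). At an unadjusted p under 0.05 the 4 lists had 5, 4, 4 and 2 lower members in this order, and DESeq2 called Stat5a and Atf3. The activation call was lost without WT replicate 2 (adjusted p = 0.075) or KO replicate 5 (0.059), the AP-1 call without WT replicate 2 (0.075), and the receptor call without WT replicate 2 (0.25), WT replicate 3 (0.11) or KO replicate 4 (0.60).

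Genes of amino acid supply and its stress response had negative medians that were called with the preset correlation alone. Of 25 genes of the ATF4 and unfolded protein response, 21 had negative estimates, with a median log2 fold of -0.22 (camera adjusted p = 6.6e-11; adjusted p = 0.43 with an estimated correlation and 0.34 with fry). Adjusted over the list alone 11 were lower, against 0 called by edgeR over all genes with all 6 libraries and 6 without WT replicate 1, 13 lower at an unadjusted p under 0.05 and 4 called lower by DESeq2. Chac1, a glutathione-degrading ATF4 target, was at 48.4 CPM ± 7.06 against 34.0 CPM ± 1.94 (WT and KO labels, SD, n = 3 each; edgeR adjusted p = 0.53; DESeq2 adjusted p = 0.0073). Named after their values were seen, Trib3 had a log2 fold of -0.68, Sesn2 one of -0.54, the serine synthesis enzyme gene Phgdh one of -0.18 and Xbp1 one of -0.22. The chaperone genes Hspa5 (log2 fold -0.10), Calr (0.04), Hsp90b1 (0.01) and Pdia4 (0.03) of this list, also named after their values were seen, changed less. Of 15 amino acid transport and mTORC1 genes, 13 had negative estimates, with a median log2 fold of -0.19 (-0.12 without WT replicate 2) that camera called (adjusted p = 4.8e-06; adjusted p = 0.43 with an estimated correlation and 0.34 with fry). Adjusted over this list alone 7 were lower, against 0 called by edgeR over all genes with all 6 libraries and 4 without WT replicate 1, 8 lower at an unadjusted p under 0.05 and 1 called by DESeq2, Sesn2. The translation repressor gene Eif4ebp1 was at 174.5 CPM ± 22.3 against 138.3 CPM ± 2.27 (SD, n = 3 each; edgeR adjusted p = 0.60). Slc7a5 and Slc3a2, which form the large neutral amino acid transporter, had log2 folds of -0.30 and -0.36 and were named after their values were seen.

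Growth and energy lists had negative medians. Of 42 ribosomal protein genes, 41 had negative estimates, with a median log2 fold of -0.13 (-0.08 without WT replicate 2) that camera called (adjusted p = 6.3e-14; adjusted p = 0.72 with an estimated correlation). Rpl27 led at a log2 fold of -0.13, and many ribosomal protein genes have processed pseudogenes, so their read assignment is uncertain. Of 28 Myc target and ribosome biogenesis genes 25 had negative estimates (camera adjusted p = 5.2e-05; adjusted p = 0.74 with an estimated correlation), led by Rrp12 at a log2 fold of -0.20. Of 22 glycolysis genes 20 did, with a median of -0.18 (camera adjusted p = 5.8e-04; adjusted p = 0.74 with an estimated correlation), and the aldolase gene Aldoa was at 1399 CPM ± 238.6 against 1182 CPM ± 67.4 (SD, n = 3 each; edgeR adjusted p = 0.70). That median was -0.29 without WT replicate 1, -0.11 without KO replicate 5 and -0.06 without WT replicate 2, where the call was lost (adjusted p = 0.093). Among hypoxia and HIF-1 targets 15 of 17 had negative estimates (camera adjusted p = 0.0047; adjusted p = 0.76 with an estimated correlation), led by the prolyl hydroxylase gene P4ha2 at a log2 fold of -1.43. The antioxidant list had 18 of 26 (camera adjusted p = 0.0031; adjusted p = 0.43 with an estimated correlation), led by Gpx4 at a log2 fold of -0.18. Nuclear-encoded oxidative phosphorylation genes had 39 of 49 (camera adjusted p = 0.0070; adjusted p = 0.79 with an estimated correlation), led by Uqcrq at a log2 fold of -0.17. With all 6 libraries no member of these 6 lists was called by edgeR over all genes or by DESeq2, while edgeR without WT replicate 1 called 1 lower in the hypoxia list and 1 lower in the antioxidant list. At an unadjusted p under 0.05 the lists had 3, 2, 0, 0, 2 and 2 lower members in this order. The Myc target call was lost without WT replicate 1 (adjusted p = 0.067) or KO replicate 5 (0.060), and the hypoxia call without WT replicate 2 (0.29), WT replicate 3 (0.072) or KO replicate 4 (0.41). The oxidative phosphorylation call was lost without KO replicate 5 (0.082), without KO replicate 6 (0.18), with sex of the mice as a term (0.094), with length and GC trends removed (0.14) and without WT replicate 1 (0.89), where its direction turned.

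Among marker lists of other splenic cells, camera called that of macrophages and monocytes. It had a median log2 fold of 1.18 over 13 genes (camera adjusted p = 0.018; adjusted p = 0.74 with an estimated correlation). Ly6c2, which memory CD8 T cells also express and which has close relatives, led it at 16.6 CPM ± 8.18 against 47.2 CPM ± 20.0 (WT and KO labels, SD, n = 3 each; edgeR adjusted p = 0.61). Lysozyme, Lyz2, was at 0.815 CPM ± 0.437 against 2.79 CPM ± 1.87, and the complement gene C1qb at 0.397 CPM ± 0.309 against 1.77 CPM ± 1.66; both were named after their values were seen. The call was lost without WT replicate 1 (adjusted p = 0.13), WT replicate 3 (0.18), KO replicate 4 (0.21) or KO replicate 6 (0.12, with a median of 0.61). B cell markers were not called (camera adjusted p = 0.11; adjusted p = 0.79 with an estimated correlation), with Ebf1 leading at a log2 fold of -0.97 (edgeR adjusted p = 0.70, and 0.043 without WT replicate 1), but passed as lower without WT replicate 1 (adjusted p = 4.2e-06), without KO replicate 6 (0.028) and with sex of the mice as a term (0.0018). In that list Cd22 was at 10.3 CPM ± 6.68 against 5.64 CPM ± 0.953, while Ighm was at 291.0 to 326.6 CPM in the 6 libraries; both were named after their values were seen. Camera called neither plasma cell (adjusted p = 0.71), dendritic cell (0.74), regulatory T cell (0.74), CD4 T cell (0.80) nor NK cell markers (0.81). Sdc1 (log2 fold 0.65) led the plasma cell list, Batf3 (-0.80) the dendritic cell list, Ikzf2 (1.12) the regulatory T cell list and Klre1 (-1.82) the NK cell list. Klre1 was the 1 gene lower in the NK cell list adjusted over the list alone. Its level was low, at 0.698 CPM ± 0.313 against 0.197 CPM ± 0.0806 (edgeR adjusted p = 0.60, DESeq2 adjusted p = 0.16). Without WT replicate 1 edgeR called 1 NK cell marker lower. Neutrophil, erythroid and platelet markers had 1, 1 and 2 genes above the low-count filter and were not tested.

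Camera did not call the remaining lists with all 6 libraries. The T cell receptor complex and CD8 list had a camera adjusted p of 0.19 and was led by Cd247, the receptor's zeta chain (log2 fold 0.16). It passed as higher without KO replicate 6 (adjusted p = 0.019). Naive and memory T cell genes had an adjusted p of 0.45, were led by Igfbp4 (log2 fold -0.70; DESeq2 adjusted p = 0.0052), and passed as higher without KO replicate 4 (adjusted p = 0.0080). In this list 4 genes were higher and 1 was lower at an unadjusted p under 0.05, DESeq2 called 1 higher and 1 lower, and edgeR without WT replicate 1 called 1 lower. Inhibitory receptors and exhaustion genes had 0.71, with the checkpoint receptor gene Havcr2 at 3.40 CPM ± 2.65 against 0.874 CPM ± 0.201 (WT and KO labels, SD, n = 3 each; edgeR adjusted p = 0.62, and 0.043 without WT replicate 1; DESeq2 adjusted p = 0.044). Apoptosis and survival genes had 0.37, led by the death receptor gene Fas (log2 fold 0.39), and without WT replicate 1 edgeR called 1 member higher and 2 lower. Fatty acid synthesis and oxidation had 0.29, led by Elovl6 (log2 fold 0.26), the TCA cycle 0.74, led by Idh2 (log2 fold 0.17), and the pentose phosphate pathway 0.90, led by Pgls (log2 fold -0.10). Mitochondrially encoded transcripts had 0.74, led by mt-Co2 (log2 fold -0.50), and passed as higher without WT replicate 1 (adjusted p = 0.044). Sex-linked transcripts had 0.98, led by Tsix (log2 fold -1.58), and passed as higher without KO replicate 6 (adjusted p = 0.012). KO replicate 6 was the only library labelled KO with high Xist counts. Without it the KO libraries were all male and the WT libraries mixed, so this pass cannot be read as a genotype difference. The median, the mean and the test did not share a sign for dendritic, CD4 T and NK cell markers, mitochondrially encoded transcripts and the TCA cycle.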

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

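The terms for sex and for the mitosis score, the fit without robust estimation and the length and GC correction were chosen after the data were seen. No paired analysis was possible because the groups share no replicate number. Ms4a4c was called in all 21 edgeR, limma and DESeq2 settings, and in 15 of the alternatives it was the only gene called. The count of genes was 10 (10 higher) without a low-count filter, 96 (64 higher and 32 lower) with DESeq2, and 3 (2 higher and 1 lower) with the mitosis score as a term, which added Dclk1 and Trbv12-1. Leaving out 1 library gave 1 to 119 genes, 1 to 52 higher and 0 to 67 lower. The 119 came without WT replicate 1, and the count was 2 without WT replicate 2, which added the pseudogene Gm14150. DESeq2 and the fit without WT replicate 1 shared 34 genes, all 34 in the same direction. Camera called 18 lists, against 0 with an estimated correlation and 0 with fry's directional test, 17 with length and GC trends removed and 12 to 19 when 1 library was left out. Under the mitosis score the log2 folds of the Map3k14 level, KO vs WT (0.0186), and of Relb (0.0259), Slc2a1 (0.0408) and Cd22 (0.123) turned positive. Leaving out 1 library gave log2 folds of -0.0461 to 0.00995 for Relb and -0.0550 to 0.0209 for G6pdx, and a median of -0.0670 to 0.0116 for the oxidative phosphorylation list. The cause was not tested for any of these. Over all alternatives, named genes other than Map3k14 newly passed the threshold in 63 cases, 33 of them with DESeq2 and 22 without WT replicate 1. Genes under a filter or left out in a setting have no value there. Lists lost their call with their direction kept in 61 cases, 36 of them under the estimated correlation and fry, and the oxidative phosphorylation list lost its call and turned without WT replicate 1. Lists gained a call in 9 cases. At this depth and with 3 libraries per label, the simulated 1.5-fold changes were recovered in 40.3% of genes. The simulated genes varied independently, without differences that many genes of a library share, so this percentage need not hold for the real libraries.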

Other observations

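The tests of a mislabelled library, of the sex of the mice, of myeloid cells, of the Map3k14 interval and of other splits for genes were chosen only after the results were seen, and so were the genes named here and the windows around Map3k14 and Ms4a4c.

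Genes of the T cell receptor chains had means apart in both directions and were not called over all genes with all 6 libraries, apart from Trbv12-1 in DESeq2 and under the mitosis score. Trbc2 was at 454.3 CPM ± 61.8 in the libraries labelled WT and 362.5 CPM ± 20.9 in those labelled KO, Trac at 265.8 CPM ± 9.08 and 231.8 CPM ± 15.6, and Trbc1 at 253.0 CPM ± 20.9 and 295.1 CPM ± 7.06 (SD, n = 3 each). For each of these genes, and for Trbv12-1, the groups did not overlap, and with all 6 libraries and genotype as the single term edgeR called none of them over all genes (adjusted p = 0.60 for Trbc2, Trac and Trbc1, and 0.48 for Trbv12-1). DESeq2 gave adjusted p of 0.16 for Trbc2, 0.30 for Trac and 0.28 for Trbc1. With the mitosis score as a term edgeR called Trbv12-1 (adjusted p = 0.016). The T cell receptor complex and CD8 list was the only 1 of 35 lists that passed fry's mixed test (adjusted p = 0.010). The smallest adjusted p of this list under the other 9 splits of the libraries was 0.083, though up to 4 other lists passed under those splits. The receptor chains resemble each other and their segments rearrange, so read assignment is uncertain, and the labels do not give the dose of the receptor transgene in either genotype, so dose and expression cannot be separated in these values.

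Some further genes had higher values in the libraries labelled KO and were picked after these were seen. The transcription factor gene Myb was at 137.4 CPM ± 32.2 against 218.5 CPM ± 24.1 (WT and KO labels, SD, n = 3 each; DESeq2 adjusted p = 0.0076; edgeR adjusted p = 0.60). Sesn3 had a log2 fold of 0.39, Id3 one of 0.47, Itm2a one of 0.77 and Gpr174 one of 0.69, none called by edgeR with all 6 libraries. DESeq2 called Myb, Sesn3 and Gpr174, and the fit without WT replicate 1 called Myb, Itm2a and Gpr174. Near Ms4a4c on chromosome 19, DESeq2 also called its relatives Ms4a4b (log2 fold 0.31) and Ms4a6b (log2 fold 0.35), and Lpxn (log2 fold 0.45). Within 10 Mb of Ms4a4c DESeq2 called 3 of 243 genes other than Ms4a4c, against 90 of 13912 elsewhere (Fisher's exact p = 0.21). Within 10 Mb of Map3k14 it called 4 of 266 genes (Igfbp4, Stat5a, Vat1 and Pecam1), against 90 of 13889 elsewhere (Fisher's exact p = 0.10). Genes of the Ifi200 cluster on chromosome 1 included Mndal, at 87.7 CPM ± 2.45 against 131.1 CPM ± 18.0 (DESeq2 adjusted p = 5.1e-05; edgeR adjusted p = 0.48). Ly6e, an interferon-stimulated surface protein gene, had a log2 fold of 0.42 (DESeq2 adjusted p = 8.5e-06; edgeR adjusted p = 0.021 without a low-count filter), and Ifit2 one of 0.61 (DESeq2 adjusted p = 0.0027).

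EdgeR called 1 gene with all 6 libraries and 119 without WT replicate 1. A term for the sex of the mice called 1 gene, which argues against sex having hidden such calls with all 6 libraries. The mitosis score as a term called 3, which argues against proliferation differences having hidden such calls with all 6 libraries. Neither count can tell whether sex or proliferation gave the 119 calls, because a term for either would remove calls it had caused. Without WT replicate 1 each label still held both sexes. Without WT replicate 1, mitosis scores were -0.387 and -0.268 in the libraries labelled WT and 0.00461 to 0.218 in those labelled KO. Of the 100 genes with the smallest p in the fit without it, WT replicate 1 lay nearer to the mean of the libraries labelled KO for 87%, and KO replicate 4, by the same measure, nearer to those labelled WT for 74%. The share nearer to the other label was 55% for KO replicate 5, 31% for WT replicate 2, 24% for KO replicate 6 and 12% for WT replicate 3, so 3 of the 6 libraries lay mostly nearer to the other label and the measure does not single out 1 library. A mislabelled library stays open on these values. WT replicate 1 and KO replicate 4 had the levels of their own label for Ms4a4c (39.6 and 94.1 CPM) and Trbv12-1 (266.7 and 129.7 CPM). Both genes were picked for their difference between these labels with all 6 libraries. Without WT replicate 1 edgeR still called both (adjusted p = 0.0017 for Ms4a4c and 0.015 for Trbv12-1). Without KO replicate 4 it called Ms4a4c alone (adjusted p = 0.0023). These are few genes, and the 2 libraries lay nearer to the other label for 87% and 74% of the 100 genes. The levels therefore do not settle whether a library is mislabelled. For the genes called, 3 against 3 libraries make 10 splits, too few for a share under 0.05; 4 splits, the real one included, gave at least the real count of 1, and the highest other gave 9, on the split of WT replicates 1 and 3 and KO replicate 6 that follows sex. With DESeq2, the split that set WT replicate 1 and KO replicates 4 and 6 apart called 388 genes against 96 for the real one, which points to a structure of the samples, although edgeR called 0 on that split against 1 on the real one.

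Camera with a preset correlation called the interferon list higher in the libraries labelled KO, but neither camera with an estimated correlation (adjusted p = 0.72) nor fry (adjusted p = 0.68) called it, so the explanations weighed here are for a difference that depends on the test. The 13 higher list members at an unadjusted p under 0.05 lay on 8 chromosomes. This argues against a chromosome segment from another strain that holds all of these genes. It cannot tell whether such a segment acted on genes outside it, so that possibility stays open. Myeloid cells in the cultures stay open. With the label means removed, the interferon score and the score of the macrophage and monocyte markers without Ly6c2 had a correlation of 0.659, with a 95% interval from -0.534 to 0.975 over 6 libraries. The summed CPM difference was 10.6 for these markers and 570.8 for the interferon list, but abundant Gbp genes that were not called hold much of the second sum, and members such as Oas1a and Cxcl10 differ by no more than the first, so the sums do not settle the source. Of the abundant myeloid genes, Lyz2 was at 2.79 CPM and C1qb at 1.77 CPM in the libraries labelled KO, and no value here gives the share of cells these levels stand for. The cells had been purified as naive CD8 T cells, and the marker with the highest values other than Ly6c2, Hmox1, which the antioxidant list also holds, was at 10.4 to 21.4 CPM, with a log2 fold of -0.33. A difference between the genotypes and differences between single cultures also stay open, and KO replicate 6 carried the highest score. For the 18 lists called by camera, 10 splits are again too few for a share under 0.05. Of these, 3 splits, the real one included, gave at least 18, and the splits other than the real one gave from 8 to 19.

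Map3k14 was at 61.5 CPM on average in the libraries labelled WT and 56.6 CPM in those labelled KO, a difference that was not called. Loss of the whole transcript in most cells is argued against, since the lower bound of the fold's 95% interval was 0.766. Removal of some exons stays open, because the table counts whole genes.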
